A study of Mus musculus with 12 samples.

How the data were processed

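Total RNA of sorted bone marrow erythroblasts was extracted with Trizol and cleaned on RNeasy columns with DNase treatment, labelled as biotinylated cRNA and hybridised to Illumina bead arrays, per the labels' protocols. GenomeStudio is named in the submitters' processing notes, and its version is not given in the sources used here. The authors deposited a table of intensity values that its name calls not normalized, with 45281 probes on 12 arrays and no detection p-values in the columns used here. Between 33.05% and 37.02% of the values per array lie below 0, so background had been subtracted before deposit, as read from the values. Array means ran from 134.5 to 247.2 and medians from 2.4 to 3.6 intensity units. A second deposited table holds the authors' processed intensity values of the same arrays on a linear scale; its columns share 1 distribution, with medians of 3.0 or 3.1, and each correlates with its own column of the first table with a rank correlation of at least 0.999985. How the authors scaled this second table is not given in the sources used here, and it served only as an alternative.

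Genotypes were taken from the sample titles, 6 arrays each. The arrays of 6 pairs, 1 and 2, 3 and 4, 5 and 6, 7 and 8, 9 and 10, and 11 and 12, centred on each gene's mean, correlated at 0.852 to 0.941, against -0.40 to 0.19 for other arrays of the same genotype, among them 4 and 5 and 8 and 9. The values of each pair were averaged and counted as 1 sample, which gave 3 samples per genotype. The comparison had been planned on 12 single arrays, which is given as an alternative. The plan also assumed detection p-values and, for the case of a table without them, set the background correction used here. Replicate numbers are not shared between the genotypes, and the labels give no litter, day or chip. Of 6 ways to match wild type with knock-in samples, matching by adjacent numbers left the smallest spread (correlations of 0.144 to 0.737), and blocks of 4 adjacent arrays were therefore added as an alternative after the data were seen.

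Intensities were corrected with limma's normexp method with an offset of 50, quantile-normalized between arrays and taken to log2, so that folds of dim genes are understated. A background limit was set on each array as the 90th percentile of the mirrored negative values, which came to 6.6 to 7.7 intensity units, and 15988 to 18227 probes per array lay above it. Kept were 16894 probes above the limit on at least 6 arrays whatever their genotype. Probe names came from the platform annotation: 34885 probes had 1 gene symbol, 18 had several and 10378 had none. Of the kept probes 14317 had 1 symbol and stood for 9388 genes, each represented by its probe with the highest mean; 2577 without a single symbol were tested apart. Entrez identifiers of 34807 probes were found in the RefSeq gene table, and 0 symbols needed an update. The genome build of the array is not given in the sources used here, so no coordinates are printed, and the RefSeq table served only for names and for the order of genes.

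Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Intervals are 95% intervals from the same model. Gene lists for pathways and for other cell types of the marrow were fixed before the data were examined; 36 with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01 and adjusted together, with camera's estimated correlation and fry as alternatives. The lower bounds for Hspa1a and Hspa1b take, on each wild type array, the higher of the probe's own value and the lowest value among probes above the limit. For 8 cell type lists the sample means were also compared by an exact two-sided permutation test over the 20 assignments of 3 samples against 3, which cannot give a p below 0.1. Named in the text are 7 genes of the cyclin E axis whatever their result; up to 8 genes per direction with the largest change among those that pass; the 3 members with the smallest p that go the way of each list that passes; and, if fewer than 10 genes pass, the 10 with the smallest p. Names outside this rule are marked as chosen after their values were seen, apart from Tfrc, the gene of the sorted surface protein, and Eif2s3y, a Y-linked gene used as a check of sex. Figures were drawn with matplotlib 3.10.9.

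The alternatives tried were no background correction, cyclic loess, 75th percentile scaling, the authors' processed values, no filter on dim probes, probes above the limit on all 12 arrays, the mean of a gene's probes, every probe by itself, array weights, eBayes with trend and robust, and each array left out. Added after the data were seen were the 12 arrays as 12 samples, the duplicate arrays as a random block, the blocks of 4 adjacent arrays, and both arrays of each sample left out.

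The procedure was tested on simulated data of 9388 genes in 3 samples against 3. It recovered 69% of 100 genes changed by a log2 value of 1 and 87% of 100 changed by 2, with 0 of the wrong sign and 7 unchanged genes called. A list shifted by 0.5 had a camera adjusted p of 2.33e-07, and 0.210 with an estimated correlation. The simulated noise held no structure shared across genes within a sample.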

Results

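Gene expression was measured in red cell precursors of mouse bone marrow, sorted as Ter119-positive (an erythroid surface protein) and CD71-high (the transferrin receptor, encoded by Tfrc). The mice carried a knock-in of cyclin E with the substitutions T74A and T393A, and the controls were wild type littermates on strain background 129. Cyclin E, encoded by Ccne1, activates Cdk2 at the start of DNA replication, and the ubiquitin ligase subunit Fbw7, encoded by Fbxw7, marks it for degradation. RNA was hybridised to 12 one-colour Illumina bead arrays, 6 of each genotype. Arrays 1 and 2, 3 and 4, 5 and 6, 7 and 8, 9 and 10, and 11 and 12 formed 6 pairs whose log2 values differed by an SD of 0.0933 to 0.139, against 0.30 to 0.447 for other arrays of the same genotype. Each pair was counted as 1 sample, so that 3 knock-in samples were compared with 3 wild type samples. The labels do not say whether the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical. Between 15988 and 18227 of 45281 probes lay above the background limit on each array, and 9388 genes were tested. The number of arrays limits the precision.

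On the first principal component, with 42.4% of the variance, arrays 5 to 8 lay near -21, arrays 1 to 4 between 1.16 and 4.09, and arrays 9 to 12 between 17.4 and 19.1. Each of these blocks of 4 arrays held both genotypes. The second component, with 28.6%, had the knock-in arrays between 9.08 and 14.2 and the wild type arrays between -20.8 and 0.818. The labels name no litter, day or chip for the arrays.

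**Figure D1:**
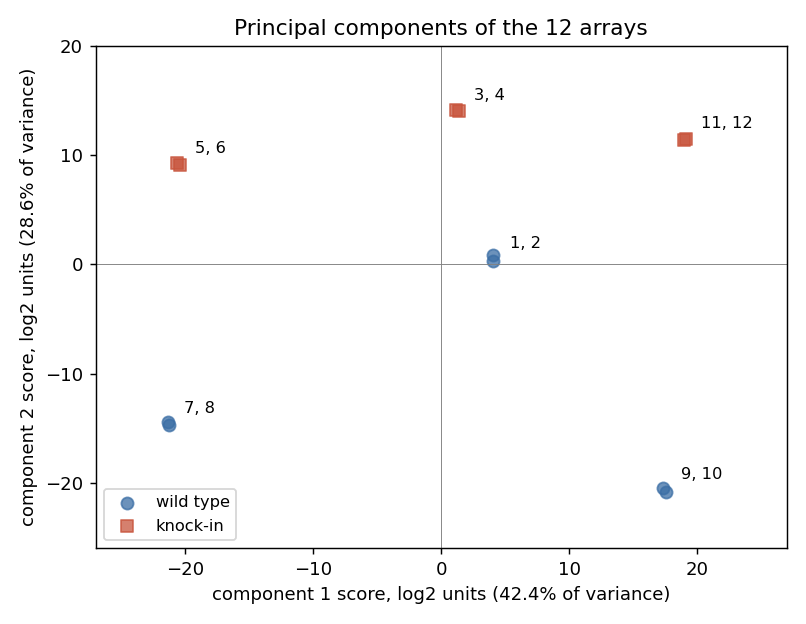
Scores of the 12 arrays on the first 2 principal components of the log2 intensities of 9388 genes, wild type as circles and knock-in as squares, with array numbers beside each adjacent pair. Adjacent arrays lie together, the first component separates blocks of 4 arrays, and the knock-in arrays lie above the wild type arrays on the second.

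The comparison asked which transcripts differ in erythroblasts whose cyclin E escapes ubiquitination through Fbw7. Expression of 8 genes rose in the knock-in samples. They were Hspa1a, an inducible cytosolic heat shock protein, Ddit4, a stress-induced inhibitor of mTORC1, Cdkn1a, the cyclin-dependent kinase inhibitor p21, Pcgf5, a Polycomb group RING finger protein, Slc30a1, a zinc exporter, Rab7b, a small GTPase of endosomal traffic, Slc19a2, a thiamine transporter, and Sap30, a subunit of the Sin3 histone deacetylase complex. Each was higher in all 3 knock-in samples than in all 3 wild type samples. No gene passed the test as lower.

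Hspa1a went from 6.10 ± 0.19 to 8.30 ± 0.17 (log2, mean ± SD, n = 3 each), with a limma adjusted p of 0.00982. Its probe was above background on 2 of 6 wild type arrays, so the rise is given as at least 4.34-fold, against the dimmest signal above background where that was the higher value on a wild type array. Its sequence is close to that of Hspa1b, a near-identical copy named here after its value was seen, whose own probe was above background on 0 of 6 wild type and 6 of 6 knock-in arrays. That probe was at least 1.40-fold higher and did not pass over all genes (limma adjusted p = 0.121). Ddit4 went from 6.74 ± 0.04 to 8.64 ± 0.19, a 3.72-fold rise (3.06 to 4.53, limma adjusted p = 0.00982). Cdkn1a went from 6.90 ± 0.16 to 8.63 ± 0.16, a 3.31-fold rise (2.66 to 4.11, limma adjusted p = 0.0194), and 2 dimmer Cdkn1a probes differed by 1.30 and 0.60. The rises of the other 5 genes, each with a limma adjusted p of 0.0358, were 2.58-fold for Pcgf5, 2.40-fold for Slc30a1, 2.07-fold for Rab7b, 2.02-fold for Slc19a2 and 1.94-fold for Sap30. Their log2 changes had standard errors of 0.13, 0.12, 0.10, 0.09 and 0.09. A second, dimmer Pcgf5 probe differed by -0.04, and with the mean of both probes the change was 0.67, and a dimmer Rab7b probe differed by 0.67. The log2 difference fitted for Hspa1a, which rests on wild type signals mostly not above background and sets no fold, was 2.20 as reported, 3.37 without background correction and 3.59 with the authors' processed values. That of Rab7b was 1.05, 1.64 and 1.73, and that of Ddit4 was 1.90 as reported and 2.52 with the authors' values. The 2 next smallest p belonged to 3110040M04Rik and Psmd10, a proteasome assembly chaperone, which differed by 1.72 and 1.00 and did not pass (limma adjusted p = 0.0526 for each). Both passed with the blocks of 4 arrays as a term, which was chosen after the data were seen (limma adjusted p = 0.034 and 0.0267). Among the probes without a single gene symbol, 2 of 2577 were called higher and 0 lower.

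At an unadjusted p under 0.05 limma found 812 genes, 522 higher and 290 lower, which is 8.65% of all genes, and the lowest adjusted p of a lower gene was 0.071. The samples of the genotypes did not overlap for 13.7% of genes, where chance gives 10% on average. Without a block term, 3 of the 9 other splits of the 6 samples into 3 and 3 gave more than 812 genes at an unadjusted limma p under 0.05. Over all these splits that count therefore does not set the genotypes apart. Each of the 3, however, put both samples of at least 1 block of 4 arrays on the same side. The other splits with 1 sample of each block on each side, as the genotypes have, gave 27, 229 and 57 genes. Such splits are too few for a test. With the blocks of 4 arrays as a term, chosen after the data were seen, limma called 63 genes higher and 25 lower, and all 8 genes were among them. The blocks are the matching that left the smallest spread, a choice that favours low p-values. The log2 changes are the same in both fits, so these calls are no separate support for the 8 genes. Hspa1a, Ddit4 and Cdkn1a passed under each other setting tried on all 6 samples in which they were tested. Under 75th percentile scaling the limma adjusted p was 0.0936 for Pcgf5 and 0.0838 for Rab7b, Slc19a2 and Sap30, and without the filter on dim probes it was 0.0534 for Slc30a1 and 0.0575 for Pcgf5. Pcgf5 also lost its call with the mean of probes (limma adjusted p = 0.209) and Rab7b with cyclic loess (0.0628). Sap30 lost its call without background correction (limma adjusted p = 0.0587), with the authors' values (0.0656) and with eBayes trend and robust (0.0707). Over all alternatives, the adjusted p of these 5 genes lay between 4.23e-07 and 0.25. Genes called higher numbered 1 without wild type arrays 1 and 2, 0 without knock-in arrays 3 and 4, 2 without knock-in arrays 5 and 6, 2 without wild type arrays 7 and 8, 4 without wild type arrays 9 and 10, and 0 without knock-in arrays 11 and 12. Of the 8 genes reported, 0, 0, 2, 1, 3 and 0 were among them, while their log2 changes stayed between 89% and 107% of the values from all samples.

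**Figure D2:**
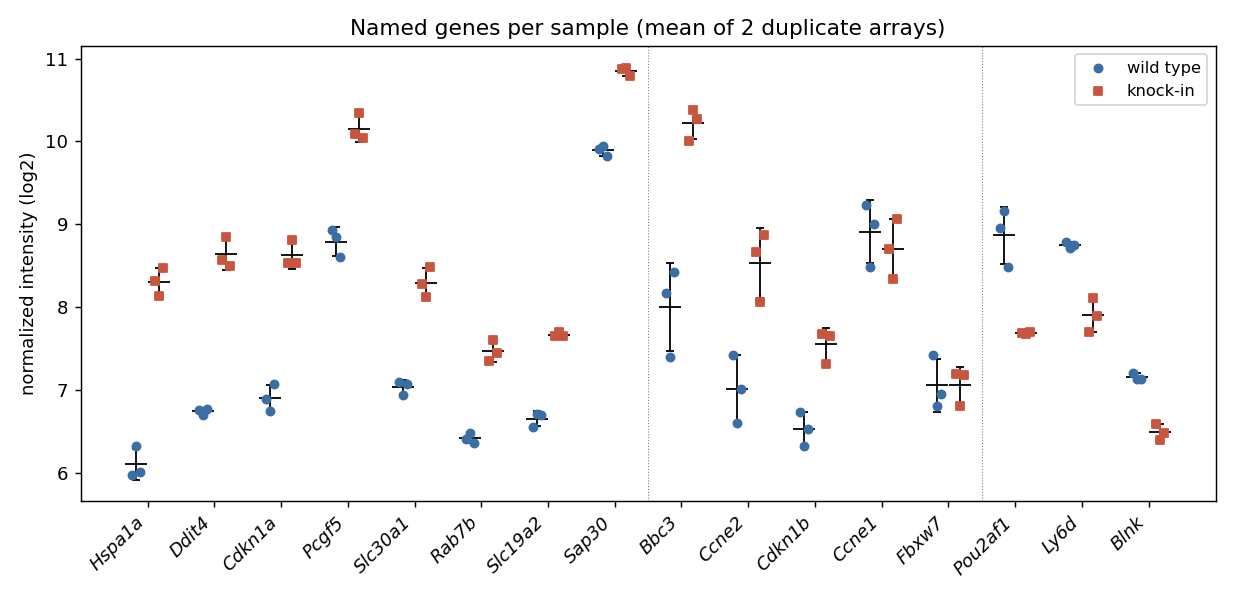
Normalized log2 intensity of 16 genes in each of 3 wild type samples (circles) and 3 knock-in samples (squares), each point the mean of 2 duplicate arrays, with black bars for the mean and SD of a genotype. The 8 genes on the left rose, and those between the dotted lines did not pass the test over all genes. The B lineage genes Pou2af1, Ly6d and Blnk on the right passed when adjusted over the list alone and not over all genes. With the blocks of 4 arrays as a term, Pou2af1 and Blnk also passed over all genes (limma adjusted p = 0.0493 each). So did Cdkn1b, Ccne2 and Bbc3 between the dotted lines (limma adjusted p = 0.0276, 0.0302 and 0.0473).

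Of 7 genes of the cyclin E axis, fixed before the data were examined, 1 passed over all genes and 3 passed when adjusted over the list alone. These 3 were Cdkn1a, Cdkn1b, which encodes the Cdk2 inhibitor p27, and Ccne2, which encodes the second E-type cyclin. Ccne1 itself was 8.91 ± 0.38 in wild type and 8.70 ± 0.36 in knock-in samples (n = 3 each), a difference of -0.21 ± 0.25 (SE, limma adjusted p = 0.952). The position of its probe relative to the substituted codons is not given in the sources used here, so the value does not check the genotype labels. Ccne2 differed by 1.52 ± 0.28, 2.87-fold, and Cdkn1b by 1.02 ± 0.15, 2.03-fold, with limma adjusted p of 0.141 and 0.113 over all genes. With the blocks of 4 arrays as a term these were 0.0302 and 0.0276. A second Cdkn1b probe differed by 0.31. Cdk2 differed by 0.28 ± 0.14, Cdkn1c by 0.24 ± 0.10 and Fbxw7 by 0.00 ± 0.19.

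Gene lists fixed before the data were examined were compared with all other genes by limma's camera test. Of 36 lists, 7 rose and 6 fell with the preset correlation of 0.01. At this setting the 9 other splits of the 6 samples into 3 and 3 called between 5 and 14 lists. With the correlation within each list estimated from these 6 samples, 0 lists passed between the genotypes, and the lowest adjusted p was 0.0762. In the lists called at the preset value, the estimates lay between -0.0195 (TCA cycle) and 0.472 (antioxidant defence). Among these lists, the sample means of the genotypes overlapped for antioxidant defence, replication-dependent histones, oxidative phosphorylation and the mitochondrial ribosome. They also overlapped for erythroid transcription factors and for mast cell, basophil and eosinophil markers, and not for the others. The directional fry test, which asks whether the genes of a list move one way, called 4: B lineage markers, cytosolic ribosomal proteins, p53 targets and cytosolic chaperones. With the blocks of 4 arrays as a term, camera called 18 lists with the preset correlation and 0 with an estimated one, and fry called 1, the TCA cycle (adjusted p = 0.00117), while its adjusted p for these 4 lists was 0.0641, 0.0828, 0.0828 and 0.129. In the samples in which these groups were measured, the mean of the B lineage markers was lower by a log2 value of -0.80 and that of mast cell, basophil and eosinophil markers by -0.36.

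p53 targets rose by a mean of 0.41 (median 0.14), with 18 of 25 members higher (camera adjusted p = 1.32e-05, and adjusted p = 0.0762 with an estimated correlation). Of them 1 passed over all genes, or 4 with the blocks as a term, and 5 adjusted over the list alone. Besides Cdkn1a, the leading members were Bbc3, which encodes the pro-apoptotic protein Puma, and Ei24, an endoplasmic reticulum protein. Bbc3 differed by 2.22 ± 0.27 (4.67-fold, limma adjusted p = 0.0753, and 0.0473 with the blocks as a term), while 2 dimmer Bbc3 probes differed by 0.41 and 0.58. Ei24 differed by 0.51 ± 0.09.

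Genes of the unfolded protein and integrated stress responses rose by a mean of 0.35 (median 0.19), with 18 of 24 higher (camera adjusted p = 4.65e-06, and adjusted p = 0.192 with an estimated correlation). Of these, 1 passed over all genes and 6 adjusted over the list alone, among them Ddit4, Slc3a2, a subunit of amino acid transporters, at 0.86 ± 0.16, and Dnajb9, an endoplasmic reticulum co-chaperone, at 0.55 ± 0.11 (0.30 on a dimmer probe). Cytosolic chaperones rose by 0.37 on average with 11 of 19 higher (camera adjusted p = 0.000315, and adjusted p = 0.192 with an estimated correlation). Their median was 0.05, and with Hspa1a and Hspa1b at their bounds the mean was 0.36 and the median 0.05. In this group 1 gene, Hspa1a, passed over all genes, or 3 with the blocks as a term, and 6 adjusted over the list alone, including the Hsp70 co-chaperones Bag3, at 0.92 ± 0.15, and Dnajb1, at 0.84 ± 0.14. Antioxidant defence genes rose by 0.12 with 13 of 24 higher (camera adjusted p = 0.0122, and adjusted p = 0.664 with an estimated correlation), with 0 members past the test over all genes and 1, Srxn1, adjusted over the list alone. Srxn1, which encodes sulfiredoxin, differed by 0.79 ± 0.16, Foxo3, a transcription factor, by 0.94 ± 0.22, and Gclc, which makes the glutathione precursor, by 0.46 ± 0.13. A dimmer Foxo3 probe differed by 0.25. The mean of the antioxidant list was 0.004 without wild type arrays 7 and 8 and 0.033 without knock-in arrays 11 and 12, and it did not pass in either case; it was 0.21 without knock-in arrays 5 and 6 and 0.23 without wild type arrays 9 and 10.

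Genes of mitosis rose by a mean of 0.41, with 24 of 25 higher (camera adjusted p = 3.84e-08, and adjusted p = 0.475 with an estimated correlation). Singly, 0 passed over all genes and 0 adjusted over the list alone, and 2, Ect2 and Ube2c, passed over all genes with the blocks as a term (limma adjusted p = 0.0476 and 0.0461). Ube2c, a ubiquitin-conjugating enzyme of mitosis, was named after its value was seen. The smallest p belonged to Tpx2, a spindle assembly factor, at 0.94 ± 0.22, Ndc80, a kinetochore protein, at 0.78 ± 0.22, and Ect2, which drives cytokinesis, at 0.73 ± 0.23. Within the blocks of 4 arrays the list differed by 0.03, 0.41 and 0.77. Replication-dependent histones rose by 0.41 with 46 of 53 higher (camera adjusted p = 2.36e-10, and adjusted p = 0.534 with an estimated correlation). Of these, 0 passed over all genes and 4 adjusted over the list alone, with H2bc4 at 0.90 ± 0.13, H1f2 at 0.74 ± 0.12 and H2ac18 at 0.78 ± 0.15. H2ac18 probes disagreed, with differences of 0.78, 1.06 and -0.11, and a dimmer H2bc4 probe differed by 0.28. Within the blocks the histone mean differed by 0.50, -0.01 and 0.74, and it was 0.26 without knock-in arrays 3 and 4 and 0.68 without knock-in arrays 5 and 6. Genes of DNA replication and the G1/S transition differed by a mean of 0.07 and did not pass (camera adjusted p = 0.225). That list passed under 1 of 13 other settings and with 2 of the 6 samples left out in turn.

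Erythroid transcription factors and genes of erythropoietin signalling rose by 0.22 with 13 of 21 higher and a median of 0.12 (camera adjusted p = 0.026, and adjusted p = 0.534 with an estimated correlation). For this list 0 members passed over all genes and 0 adjusted over the list alone. Gfi1b and Tal1, transcription factors of the erythroid lineage, differed by 0.85 ± 0.23 and 0.79 ± 0.23, and Pim1, a kinase induced by Stat5, by 1.14 ± 0.33 (limma adjusted p = 0.0493 with the blocks as a term). The list did not pass with array weights (mean 0.21), without wild type arrays 7 and 8 (0.17) or without knock-in arrays 11 and 12 (0.16). Red cell membrane and late erythroid genes differed by 0.19 (camera adjusted p = 0.0527), globins by 0.02 (0.543), heme synthesis by -0.03 (0.926) and iron handling by 0.05 (0.526). The late erythroid list passed as higher with the blocks as a term (camera adjusted p = 0.0111, and adjusted p = 0.689 with an estimated correlation), under 5 of 13 other settings in all, and with 4 of the 6 samples left out in turn. Tfrc, the gene of the surface protein used for the sort, was 11.87 ± 0.86 in wild type and 12.28 ± 0.37 in knock-in samples, a difference of 0.40 ± 0.43.

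**Figure D3:**
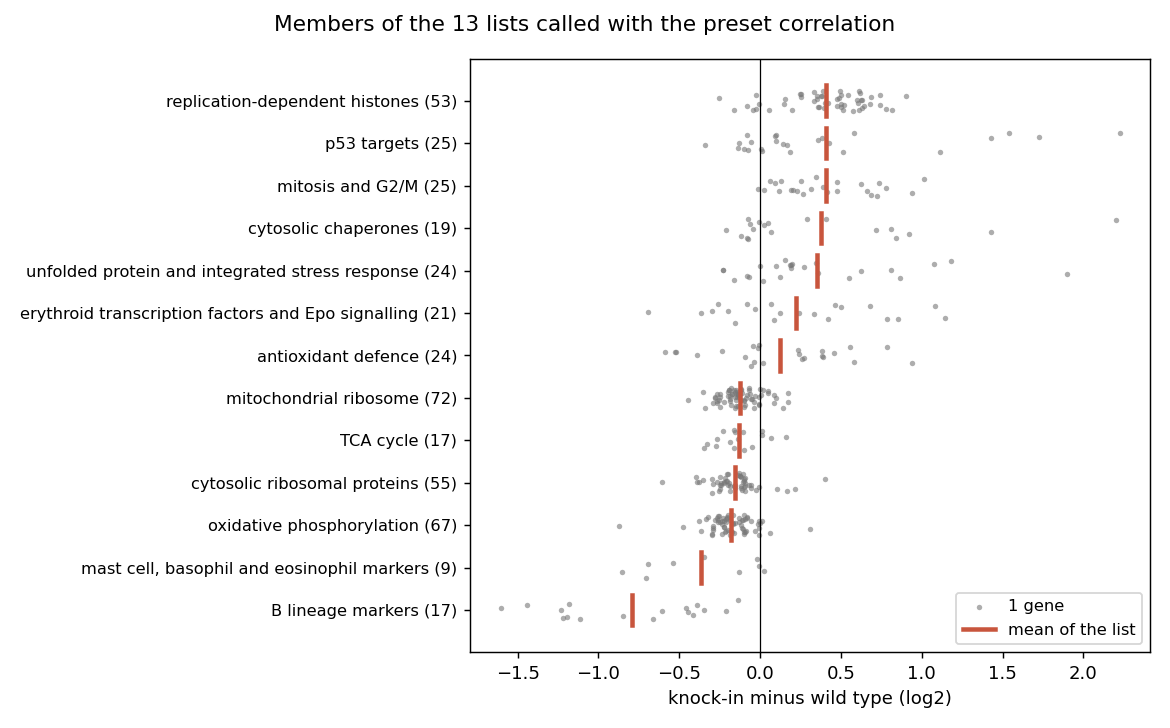
Log2 difference, knock-in minus wild type, of each measured member (grey points) and the mean (bar) of the 13 gene lists that camera called with the preset correlation, with the number of members in brackets. The B lineage markers have the lowest mean, -0.80, and 0 lists passed with an estimated correlation; the means of the ribosomal, oxidative phosphorylation, mitochondrial ribosome and TCA cycle lists change sign under 75th percentile scaling.

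B lineage markers fell by a mean of 0.80, the lowest of the 36 lists, and all 17 measured members were lower (camera adjusted p = 2.03e-14, and adjusted p = 0.0762 with an estimated correlation). The list mean was 9.00 ± 0.17 in wild type and 8.20 ± 0.07 in knock-in samples (n = 3 each), and within the blocks it differed by -0.86, -0.90 and -0.63. No member passed over all genes, or 3 with the blocks as a term, and 10 passed adjusted over the list alone. They included Blnk, an adaptor of B cell receptor signalling, at -0.66 ± 0.09, Ly6d, a surface protein of B cell progenitors, at -0.85 ± 0.12, and Pou2af1, a B cell transcriptional coactivator, at -1.18 ± 0.18. An exact two-sided permutation test of the list means gave p = 0.1, the smallest that 3 samples against 3 allow, and 0.533 after adjustment over 8 cell type lists.

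Markers of mast cells, basophils and eosinophils fell by 0.36 with 8 of 9 lower (camera adjusted p = 0.0111, and adjusted p = 0.534 with an estimated correlation). Here 0 members passed over all genes and 0 adjusted over the list alone, and the list did not pass without wild type arrays 7 and 8, when its mean was -0.22. With the blocks as a term, 2 of them passed over all genes, Mcpt8 and Prss34 (limma adjusted p = 0.0493 each), the latter named after its value was seen. Mcpt8, a basophil protease, differed by -0.69 ± 0.18, and the eosinophil granule genes Prg2 and Epx by -0.54 ± 0.17 and -0.85 ± 0.28. Neutrophil and granulocyte precursor markers had a mean of 12.30 ± 0.30 in wild type and 12.30 ± 0.38 in knock-in samples. Red cell membrane and late erythroid genes had means of 10.80 and 10.98. RNA of other marrow cells was thus present in the sorted samples despite the gate for Ter119 and CD71. The changes given here are therefore those of the sorted samples, and erythroblasts were not measured alone. Markers of T and NK cells differed by -0.22 (camera adjusted p = 0.0527), of stromal and endothelial cells by -0.31 (0.0574), of monocytes and macrophages by -0.18 (0.389), of early erythroid cells and progenitors by -0.14 (0.253), and of megakaryocytes and platelets by -0.07 (0.543). With the blocks of 4 arrays as a term, 3 of these passed as lower, T and NK cells (camera adjusted p = 0.0172), stromal and endothelial cells (0.00971) and monocytes and macrophages (0.0327), each with adjusted p = 0.466 with an estimated correlation. The T and NK list passed under 8 of 13 other settings and the stromal list under 5 of 12. Each passed with 3 of the 6 samples left out in turn. The T and NK mean then lay between -0.368 and -0.089 and the stromal mean between -0.421 and -0.165.

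Genes of oxidative phosphorylation fell by a mean of 0.18, with 63 of 67 lower (camera adjusted p = 9.16e-07, and adjusted p = 0.555 with an estimated correlation), but the mean was 0.04 under 75th percentile scaling. Cytosolic ribosomal proteins fell by 0.16 with 51 of 55 lower (camera adjusted p = 2.78e-06, and adjusted p = 0.0762 with an estimated correlation), and the mean was 0.02 under that scaling. Mitochondrial ribosomal proteins fell by 0.12 with 61 of 72 lower (camera adjusted p = 0.00115, and adjusted p = 0.664 with an estimated correlation), against 0.04 under that scaling. Genes of the TCA cycle fell by 0.13 with 13 of 17 lower (camera adjusted p = 0.00979, and adjusted p = 0.192 with an estimated correlation), against 0.01 under that scaling. In each of these 4 lists 0 members passed over all genes and 0 adjusted over the list alone. In the oxidative phosphorylation list Ndufs3 and Uqcrc2, subunits of complexes I and III, differed by -0.34 ± 0.13 and -0.30 ± 0.12, and Ndufb10 by -0.87 ± 0.34 on its brighter probe, which passed with the blocks as a term (limma adjusted p = 0.0493), and 0.69 on the other. The list mean was -0.11 without knock-in arrays 5 and 6 and -0.11 without wild type arrays 9 and 10. In the TCA cycle Idh3g differed by -0.33 ± 0.09, Fh1 by -0.27 ± 0.09 (-0.12 on a dimmer probe) and Idh3b by -0.27 ± 0.11. Among ribosomal proteins Rps10 differed by -0.30 ± 0.08, Rpl22 by -0.38 ± 0.11 and Rps15 by -0.39 ± 0.13, and in the mitochondrial ribosome Mrps9 differed by -0.28 ± 0.10, Mrps23 by -0.25 ± 0.10 and Mrps21 by -0.34 ± 0.14. The TCA list also did not pass with the authors' processed values (mean -0.14) or without knock-in arrays 5 and 6 (-0.11), and the mitochondrial ribosome list without knock-in arrays 5 and 6 (-0.05) or wild type arrays 9 and 10 (-0.05). The latter list was at -0.19 without knock-in arrays 11 and 12.

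In all, 23 lists did not pass; in 8 of them 1 member passed adjusted over the list alone, and 0 passed over all genes in any. Besides those given with their neighbours, immediate early genes differed by 0.20 (camera adjusted p = 0.0574), the interferon response by 0.12 (0.104), DNA damage response and repair by 0.09 (0.183), cholesterol synthesis by 0.07 (0.242), and autophagy and mitophagy by 0.05 (0.443). Immediate early genes passed under 3 of 13 other settings and with 4 of the 6 samples left out in turn. The interferon list passed under 3 of 13 other settings, among them the blocks (camera adjusted p = 0.0109, and adjusted p = 0.466 with an estimated correlation), and with 2 of the 6 samples left out in turn. With samples left out, its mean lay between 0.027 and 0.248 and that of autophagy and mitophagy between 0.01 and 0.105. The DNA damage list passed under 0 of 13 other settings and with 2 of the 6 samples left out in turn. Fatty acid oxidation differed by -0.08 (camera adjusted p = 0.228), ribosome biogenesis and Myc targets by -0.07 (0.193), and mitochondrial biogenesis by -0.06 (0.242). Enucleation and chromatin condensation genes had a mean of 0.14 and a median of -0.06 (camera adjusted p = 0.412), apoptosis genes 0.08 and -0.02 (0.807), the proteasome 0.04 and -0.01 (0.915), and glycolysis 0.00 and -0.03 (0.994). For 7 lists the median, the mean and the test differed in sign: these last 4, heme synthesis, neutrophil markers, and megakaryocyte and platelet markers. Plasma cell markers had 2 measured members and were not tested.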

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

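The tests that counted 12 arrays as samples, blocked the duplicates or the adjacent arrays, or left out whole samples were chosen only after the data were seen. The number of genes called higher, 8 as reported, was 15 without background correction, 20 with the authors' processed values, 14 with every probe by itself, 34 with array weights and 16 with eBayes trend and robust. It was 536 with 12 arrays as 12 samples, 237 with the duplicate pair as a random block and 63 with blocks of 4 adjacent arrays. The number called lower, 0 as reported, was 1 with the authors' processed values, 1 with the mean of probes, 10 with array weights, 324 with 12 arrays as 12 samples, 46 with the random block and 25 with blocks of 4. Counting duplicates as samples raises the number of samples by construction; otherwise the cause was not tested. Leaving out arrays or samples gave 0 to 11 genes higher and 0 to 2 lower. The number of lists called, 13 as reported, was 0 with an estimated correlation and 4 with fry, and between 12 and 18 under the other settings in which lists were tested and with arrays or samples left out.

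Under 75th percentile scaling the mean turned positive for oxidative phosphorylation (0.037), the TCA cycle (0.011), mitochondrial biogenesis (0.049), the mitochondrial ribosome (0.038), heme synthesis (0.178), cytosolic ribosomal proteins (0.015), ribosome biogenesis and Myc targets (0.064) and fatty acid oxidation (0.064). The median change of all genes was 0.03 under this scaling and -0.03 as reported. Before normalization, array means were higher in knock-in than in wild type arrays within each block of 4. They were 190.7 and 184.6 against 169.7 and 172.3, 247.2 and 230 against 193.8 and 198.6, and 184.3 and 178.3 against 134.5 and 144.4. Quantile normalization gives all arrays 1 distribution, so the reported changes are relative to the signal of the whole array. The cause of the sign changes was not tested further. Other lists that changed sign were near 0 and not called. Neutrophil markers had a mean of -0.010 without background correction, -0.015 with cyclic loess, -0.012 with the authors' values and -0.001 with the mean of probes. Globins had -0.006 with cyclic loess, -0.061 with probes above the limit on all arrays, -0.024 with the mean of probes and -0.001 with array weights. Heme synthesis had 0.001 with cyclic loess, and glycolysis -0.002 with the authors' values.

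With arrays or samples left out, the mean lay between -0.058 and 0.089 for glycolysis, -0.15 and 0.21 for neutrophil markers, -0.198 and 0.087 for heme synthesis, -0.087 and 0.438 for immediate early genes, -0.032 and 0.19 for DNA replication, and -0.03 and 0.095 for iron handling. It lay between -0.059 and 0.379 for late erythroid genes, -0.015 and 0.084 for the proteasome, -0.017 and 0.175 for DNA damage response, -0.345 and 0.039 for monocytes, -0.172 and 0.025 for megakaryocytes, and -0.042 and 0.039 for globins. Fbxw7 lay between -0.125 and 0.181. No named gene reversed in the 674 comparisons with other settings. Of these comparisons, 565 kept their side of the threshold, 11 lost the call and 98 gained one. Some settings, such as eBayes with trend and robust or the blocks of adjacent arrays, leave the log2 change as reported, so no reversal was possible there. Others count each array as a sample or take the duplicate pair as a random block, and these called 536 and 237 genes higher. The tally is therefore partly fixed by the choice of settings.

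The genotypes share no replicate numbers in the labels, so pairing rests only on the array numbers: the fit with blocks of 4 pairs 1 wild type with 1 knock-in sample in each block. A chip term was not run because no chip is named. A sex covariate was not run because the brighter probe of the Y-linked gene Eif2s3y was above background on all 12 arrays. A dimmer Eif2s3y probe was above background on 5 arrays. A Y-linked signal on each array does not exclude samples that mix the sexes. Dim genes are limited by signal over background, as for Hspa1a in wild type.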

Other observations

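The test with blocks of adjacent arrays (for genes, lists, the B lineage gap and the neighbours of Ccne1) and both tests on the B lineage markers were chosen only after the result was seen. With blocks of 4 adjacent arrays as a term, further genes passed that had not passed without it, and those named here were chosen after their values were seen. Plek2, a pleckstrin of the erythroid cytoskeleton, was higher by 2.17 ± 0.12 (SE, limma adjusted p = 0.0267 with the blocks and 0.121 without), with 1.92, 2.41 and 2.19 in the 3 blocks. Irs2, an adaptor of the insulin receptor, was higher by 1.32 ± 0.08 (limma adjusted p = 0.0267 with the blocks and 0.0793 without). Clk1, a kinase of splicing factors, Hsp90aa1, the inducible cytosolic Hsp90, and Trp53inp1, a p53-induced nuclear protein, were higher by 1.54, 1.43 and 1.43. Among lower genes were the B cell genes Cd79b (-1.12), Mzb1 (-0.91) and Siglecg (-0.86, also among the 40 tested genes nearest to Ccne1), and Aldh1a1 (-1.02), which encodes a retinaldehyde dehydrogenase.

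Members of the p53 list were not moved alike. Ccng1, which encodes cyclin G1, differed by 1.12 ± 0.22 and passed adjusted over the list alone, and over all genes with the blocks as a term (limma adjusted p = 0.0267). Mdm2, the ubiquitin ligase of p53, differed by 0.58 ± 0.36 and Phlda3 by 1.54 ± 0.93, both within their spread. The p53 targets Pmaip1, Fas and Gadd45a differed by -0.06 ± 0.09, -0.08 ± 0.27 and -0.34 ± 0.13. Of the immediate early genes Ier3 differed by 1.19 ± 0.43, Dusp1 by 0.97 ± 0.18, Jund by 0.80 ± 0.22, Fos by -0.31 ± 1.04 and Egr1 by 0.01 ± 0.45. Dusp1 passed adjusted over the list alone, and over all genes with the blocks as a term (limma adjusted p = 0.0302). All genes of this paragraph were chosen after their values were seen.

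The rise of 8 genes was set against the other splits of the 6 samples and against 2 technical explanations. The 10 splits of 6 samples into 3 and 3 are too few for a share under 0.05: the genotypes gave 8 genes and the highest of the others gave 1, so that 1 split of 10 reached 8. The splits were fitted without the blocks of 4 arrays. The genotypes are balanced over these blocks and some of the other splits are not, so the counts are not fully alike. With the mean of immediate early genes per sample as a covariate, the median change of the 8 genes was 1.33, against 1.31 without it, and with the mean of late erythroid genes it was 1.30; these covariates moved 12.5% and 19.7% of all genes, and all 8 genes kept an unadjusted p under 0.05. Both list means overlapped between the genotypes, and the 8 genes were chosen by p in these same samples. The rise could therefore hardly be lost to either covariate, and the values show only that it did not follow these 2 means. Both lists passed as higher with 4 of the 6 samples left out in turn. Handling stress and maturation, such as stress that moves Ier3, Dusp1 and Jund and not the rest of their list, and an effect of the genotype itself, stay open.

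The lower B lineage markers could come from fewer B lineage cells, or less of their RNA, in the knock-in sorts. A Ter119-positive gate is meant to remove such cells, yet signal of other cells remained. Neutrophil and granulocyte precursor markers averaged 12.30 in both genotypes, and the B lineage gene Cd79b was at 10.38 in wild type samples. A lower share of all non-erythroid cells stays open: the gap between the B lineage mean and the mean of neutrophil, T and NK, and monocyte markers differed by -0.66 (95% interval -1.10 to -0.22), but by -0.90, -0.79 and -0.29 within the blocks, with an interval of -1.47 to 0.15 that holds 0. The scaling between arrays was argued against, since over 4 scalings the mean came no nearer to 0 than -0.649. None of the 17 list members is in another list. The brighter ones, Cd74 and H2-Ab1, which other antigen-presenting cells also express, went from 12.25 to 11.79 and from 11.67 to 11.28. Both were named after their values were seen. Whether the genotype itself or the content of other cells sets the difference stays open.

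For the 13 called lists the 10 splits are likewise too few for a share under 0.05: 2 gave 13 or more lists, and the highest of the others, with 14, put arrays 1 to 4 and 11 to 12 against the rest. The 9 other splits called between 5 and 14 lists, so calls at the preset correlation also arose when the genotypes were mixed. At an unadjusted p under 0.05, 3 of the 9 other splits gave more genes than the 812 of the genotypes: arrays 1, 2 and 9 to 12 against 3 to 8 (1521), arrays 1, 2 and 5 to 8 against the rest (1150), and arrays 1 to 4, 11 and 12 against the rest (1117), which points to a structure of the samples. These fits held no block term, and each of these 3 splits put both samples of at least 1 block on the same side. The other splits with 1 sample of each block on each side, as the genotypes have, gave 27, 229 and 57 genes. With the blocks as a term the genotypes gave 1597 genes, and the other splits were not fitted that way. Strain variants carried along with the knock-in allele were argued against as a broad effect, since 3 of the 40 tested genes nearest to Ccne1 in gene order had an unadjusted p under 0.05 (Fisher's exact one-sided p = 0.685 against all other genes), and 7 did with the blocks as a term (exact p = 0.533). One of the 3 is the B lineage marker Spib (-0.60 ± 0.11), and the others are Garre1 (0.85) and Cebpg (0.47), all named after their values were seen. A count over 40 genes cannot show a variant at single genes, which stays open. Without Spib the B lineage mean was -0.81.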
